A study of Homo sapiens with 8 samples.

How the data were processed

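Human aortic endothelial cells (HAEC) and human bronchial epithelial cells (HBEC), both primary cells in culture, were exposed for 3 h to 10 ug/mL of ambient particulate matter (APM) from summer or winter, or to a water control of the same season. One Affymetrix human genome array (U133 A 2.0) was run for each cell type, season and treatment, which gives 8 arrays and 4 pairs of an APM array with its own water array. The labels do not say whether the seasons or the arrays come from separate cultures or donors. The p-value of a gene therefore measures only the spread between these samples. The p-value of a gene list measures mainly the spread between genes, as described below.

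The deposited table holds 1 linear signal intensity for each of 22277 probe sets and each array. Per the labels the authors used GCOS, the Affymetrix operating software. Its version, algorithm settings and scaling target are not given in the sources used here. The 2%-trimmed mean of the deposited intensity ran from 74.68 to 243.6 between arrays, so the values had no common scale. The number of arrays limits the precision, and no detection calls were used here.

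Each array was scaled to the average trimmed mean of 143.24, and log2 was taken after adding 14.32, which is 10% of that mean. Levels are given as scaled intensity, and changes on the log2 scale include the added 14.32, so that changes of dim genes are drawn toward 0. Of the probe sets, 19070 carried 1 gene symbol, 1043 carried several and 2164, among them 62 Affymetrix controls, carried none. Probe sets with 1 symbol stood for 11939 genes, each represented by its probe set of highest mean. Sex-linked transcripts (31 probe sets) were left out. Genes were kept when their mean over the 8 arrays reached 19.81, the 40th percentile of all probe sets, which left 7836 genes. A gene is called dim in a cell type when its mean over that cell type's 4 arrays was under this level.

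Responses were fitted in R 4.3.3 with limma 3.58.1, by lmFit and eBayes over all 8 arrays, with each water and APM pair as a fixed block. The contrasts were the APM effect in HAEC, in HBEC, their difference, the effect over both cell types, the effect in summer, in winter, and the season difference as winter minus summer. Each contrast within a cell type or season rests on 2 pairs, and its error on 2 residual degrees of freedom, or 3 for the contrast over both cell types, with a moderated variance. The baseline contrast set HAEC water against HBEC water with a season term. P-values were adjusted by Benjamini-Hochberg and read at 0.05. Single pairs have 1 array per condition and carry no test.

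Gene lists were tested with limma's camera and its preset inter-gene correlation of 0.01. This test sets the genes of a list against all other genes, so its p-values measure mainly the spread between genes. It does not take its degrees of freedom from the pairs. There were 32 lists of pathway genes and cell type markers, of which 30 had 5 or more kept genes and were tested. Leukocyte and lymphatic endothelial markers were too few to test. Camera with an estimated correlation was run beside it, and it takes only the 2 or 3 residual degrees of freedom. In single pairs a list's median was placed among 10000 random lists matched on expression. A gene was named by rule: in each contrast the 10 genes of largest log2 change each way among those past the adjusted threshold with 1 sign in every pair, filled up by genes of unadjusted p under 0.05. For each list the rule takes up to 4 members of largest change, and for each single pair the 5 genes of largest change each way. CYP1A1, CYP1B1, HMOX1, CXCL8, IL6, F3, SELE, PECAM1 and KRT5 were always eligible. The contrasts, filters, lists, naming rule and most alternatives were chosen before the data were examined.

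The procedure was tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale among 7836. Between 84% and 100% of the changes of 1 and 100% of the changes of 2 were recovered, with 8 to 23 false calls per comparison. Each simulated change was equal in every pair that received it, and the many changed genes ease the adjusted threshold. A real gene can miss that threshold at a larger change, as CCL20 did in HBEC (1.66 ± 0.21, limma adjusted p = 0.397). These rates therefore do not show that a count of 0 called genes means no changes of this size. A simulated list of 20 genes shifted by 0.2 was called in every contrast except the cell type difference (adjusted p = 0.0719), and 0 of 29 other lists were called. The simulated noise was independent between genes, so this check cannot show how often lists of correlated genes are called falsely.

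Alternatives were quantile scaling, equal array medians, added offsets of 2% and 20% of the trimmed mean, no filter and a filter at the 60th percentile, the mean of all probe sets of a gene, and leaving out probe sets of the less specific _s_at and _x_at kinds. Others were a mean-variance trend in eBayes, the fit with no replicate block, an added APM effect per cell type for the season difference, the baseline without the season term, other fold thresholds, an estimated inter-gene correlation, and leaving out each array in turn. A filter on the cell type's own arrays and called lists without their member of largest change were added after the data were seen. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.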

Results

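Transcript levels were measured on 8 arrays, 1 for each combination of cell type (HAEC or HBEC), season (summer or winter) and treatment (APM or water). The 2%-trimmed mean intensity was 74.68 for the summer HAEC water array and 89.8 for its APM array, and 243.6 and 230.5 for the winter HAEC water and APM arrays. It was 133.9 and 151.1 in the summer HBEC pair, and 117.7 and 104.6 in the winter HBEC pair. The ratio of 3-prime to 5-prime signal ran from 0.905 to 1.11 for GAPDH and from 1.04 to 1.28 for ACTB. After scaling, the 95th percentile of 27 Bacillus control probe sets, which match no human transcript, was 4.6 to 8.94. Errors given are standard errors of limma fits, and each change within a cell type or a season rests on n = 2 pairs. Each error is pooled over all 4 pairs, so an error in HAEC also holds the disagreement of the HBEC pairs, and the reverse. The same holds for summer and winter. CYP1A1 was at 1.65 and 1.22 in the HAEC pairs and at 0.11 and 2.21 in the HBEC pairs, yet its error is 0.44 in both cell types.

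The baseline comparison asks how far apart the 2 cell types were before any particles. HAEC water arrays were higher in endothelial genes, with PECAM1, an adhesion molecule of endothelial junctions, up by 7.19 ± 0.4 log2 units (adjusted p = 5.61e-05) and VWF, the clotting protein von Willebrand factor, by 6.54 ± 0.25 (adjusted p = 1.49e-05). HBEC were higher in keratins of basal and squamous epithelium, with KRT5 at -8.65 ± 0.2 and KRT14 at -8.78 ± 0.19 (adjusted p = 5.25e-06 for both). In the cell type without them these genes were near or under the level of the Bacillus controls, so the added 14.32 sets the exact size and the true differences may be larger. Among the marker lists, 21 of 22 endothelial genes were higher in HAEC, and 23 of 23 basal, 18 of 19 squamous and 7 of 7 ciliated or secretory genes were higher in HBEC. HAEC also had the higher level of 29 of 34 cell cycle genes, while 16 of 23 hypoxia and glycolysis genes and 11 of 20 cholesterol genes were higher in HBEC. None of the 22 leukocyte markers reached the filter level (0 kept), and 4 of the 8 lymphatic markers were kept. In limma 3134 of 7836 genes differed, 1733 higher in HAEC and 1401 higher in HBEC. This fit used all 8 arrays with no pair block, though the water and APM arrays of a pair are much alike. Their r was 0.988 to 0.993, against 0.954 to 0.974 between the seasons of a cell type. Its errors may therefore be too small and the count too high. The count was 2057 without the winter HAEC water array, and 1831 without the less specific probe sets, where fewer genes were tested.

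The HAEC comparison asks which endothelial genes respond to APM within 3 h, with systemic inflammation as the interest named in the series description. CYP1A1, a monooxygenase induced through the aryl hydrocarbon receptor (AhR), had the largest difference, 1.43 ± 0.44 log2 units, from a scaled intensity of 327 to 1060 in summer and from 611 to 1440 in winter. Inflammatory and signalling genes were also higher: PTGS2, the inducible cyclooxygenase, at 1.02 ± 0.17, SELE, the leukocyte-binding E-selectin, at 0.94 ± 0.13, and VIPR1, a receptor for vasoactive intestinal peptide, at 1.17 ± 0.19. The size of the VIPR1 difference is uncertain, because its summer water array, at 4.39, was under the 95th percentile of the Bacillus controls there (7.75). The serotonin receptor HTR2B (0.89 ± 0.15) was higher in both pairs. Lower in both pairs were TFAP4 (-0.79 ± 0.27), KAT2A, a histone acetyltransferase (-1.34 in summer but only -0.15 in winter), and PYCR3, an enzyme of proline synthesis (-0.74 ± 0.25), though TFAP4 and PYCR3 were at background in the summer APM array. None of these genes passed the test after adjustment.

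Among the lists in HAEC, 4 rose. Targets and feedback genes of the transcription factor NF-kB rose with 9 of 15 members higher in both pairs, where chance gives 25% each way (adjusted p = 0.0151; adjusted p = 0.886 with an estimated correlation). PTGS2, NFKB2 (0.36 in summer, 0.67 in winter) and IER3 (0.35 and 0.23) were among them. Cytokines and chemokines rose with 8 of 14 members higher in both pairs (adjusted p = 0.0271; adjusted p = 0.886 with an estimated correlation), among them the neutrophil attractant CXCL2 (1.11 and 0.42), the monocyte attractant CCL2 (0.90 and 0.36) and CXCL8 (0.19 and 0.50). The AhR list rose with 7 of 13 members higher in both pairs (adjusted p = 0.0306; adjusted p = 0.886 with an estimated correlation), and ALDH1A3 was at 0.97 and 0.12. The unfolded protein response list rose with 8 of 23 members higher in both pairs (adjusted p = 0.0271; adjusted p = 0.916 with an estimated correlation). This call rests on the winter pair, where the median was 0.24 against -0.03 in summer, and its adjusted p reached 0.825 with an array left out. Its members of largest difference were CHAC1 (0.54 and 1.07), ATF3 (1.03 and 0.43), PPP1R15A (0.28 and 0.65) and DNAJC3 (-0.07 and 0.63). CHAC1, ATF3 and PPP1R15A are transcripts of the integrated stress response. The chaperone genes of the list were also raised in the winter pair, with a median of 0.13 and 10 of 12 higher. The adhesion list was not called (adjusted p = 0.555), with a median of -0.04 and a mean of 0.07, yet SELE and ICAM1 (0.48 and 0.49) passed when adjusted over the list alone. HMOX1, the heme oxygenase of oxidative stress, was at 0.30 and 0.38, IL6 at 0.23 and 0.35, F3, the clotting initiator tissue factor, at 0.90 and 0.44, and PECAM1 at -0.02 in both seasons.

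By limma 0 of 7836 genes passed in HAEC, with 386 at an unadjusted p under 0.05 where 392 are expected by chance. Adjusted over the list alone, PTGS2 passed in the NF-kB list and JUNB in the immediate early list, beside 0 over all genes. So did ELF3 and TRIM29, the latter dim in HAEC, among the basal epithelial markers. With no replicate block the gene count was also 0. Without either winter HAEC array 1 list was called, without either summer HAEC array 6, and 0 when each called list lost its member of largest difference.

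**Figure D1:**
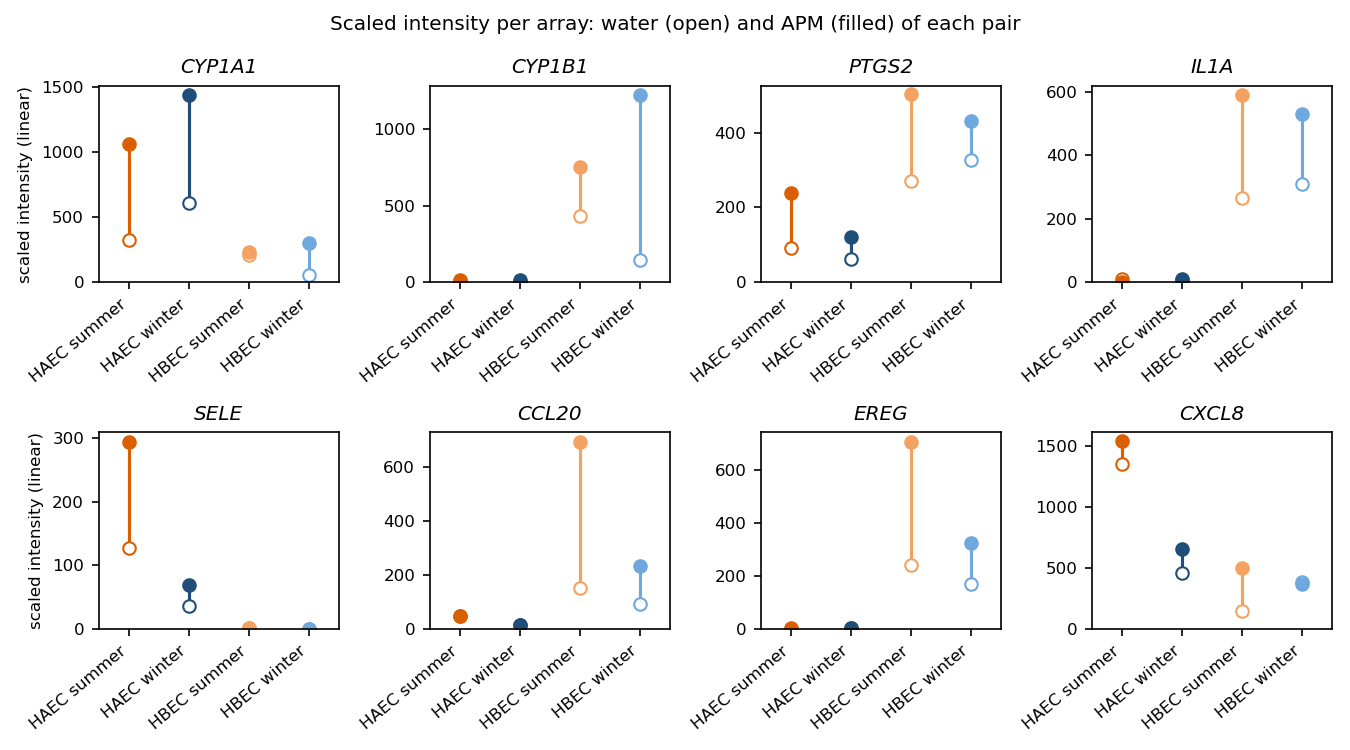
Scaled intensity (linear axis from 0) of 8 genes in each pair of arrays; open circles are water arrays, filled circles APM arrays, and each line joins the arrays of 1 pair. CYP1A1 went from 327 to 1060 in the summer HAEC pair and CYP1B1 from 142 to 1220 in the winter HBEC pair, while CCL20, EREG and IL1A were higher in HBEC and SELE in HAEC.

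The HBEC comparison asks the same of airway epithelial cells. CYP1B1 and CYP1A1, both AhR targets, were 1.88 ± 0.46 and 1.16 ± 0.44 log2 units higher, most of it in winter, where CYP1B1 went from 142 to 1220 and CYP1A1 from 53.9 to 302. CCL20, which attracts dendritic cells and lymphocytes, was 1.66 ± 0.21 higher, from 150 to 693 in summer and from 91.1 to 231 in winter. EREG, a ligand of the EGF receptor, was 1.19 ± 0.16 higher, and the interleukin genes IL1A and IL1B 0.93 ± 0.2 and 0.83 ± 0.28. The tight junction gene CLDN4 (0.81 ± 0.13) and the complement inhibitor CD55 (0.78 ± 0.15) were also higher in both pairs. Another CD55 probe set of similar brightness in HBEC was at only 0.24 in summer and 0.30 in winter, against 0.55 and 1.01 for the one used. ID3, a transcriptional inhibitor of the TGF-beta and BMP pathway, was lower by nearly equal amounts in both pairs, at -0.86 and -0.87, and CD320, the receptor for cobalamin uptake, stood at -0.92 ± 0.12.

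In HBEC 4 of 30 lists rose. Immediate early genes, the fast transcriptional response to growth factors and stress, rose with 14 of 25 members higher in both pairs (adjusted p = 0.000345; adjusted p = 0.841 with an estimated correlation), with SRF at 0.93 in summer and 0.60 in winter, DUSP5 at 1.09 and 0.18 and PPP1R15A at 1.04 and 0.01. The NF-kB list rose with 7 of 15 members higher in both pairs (adjusted p = 0.00262; adjusted p = 0.841 with an estimated correlation), with PTGS2 at 0.85 and 0.38 and TNFAIP2 at 0.45 and 0.58. Cytokines and chemokines rose with 5 of 14 members higher in both pairs (adjusted p = 0.00617; adjusted p = 0.841 with an estimated correlation). Their members split by season, since CCL20, IL1A and IL1B were higher in both pairs while CXCL8 was at 1.64 in summer and -0.04 in winter. EGF receptor ligands and feedback genes rose with 3 of 9 members higher in both pairs, EREG, TGFA (0.47 and 0.54) and PHLDA1 (0.70 and 0.26) (adjusted p = 0.0121; adjusted p = 0.841 with an estimated correlation). HBEGF was at 1.02 in summer and -0.19 in winter. Fibroblast genes were not called (adjusted p = 0.124), though FAP (-0.67 and -0.95), POSTN (-0.27 and -0.64) and the dim COL1A2 (-0.52 and -0.70) passed when adjusted over the list alone. So did MCM2 (-0.54 and -0.85), a DNA replication gene, in the cell cycle list. HMOX1 was at -0.34 and 0.33, and its mean of -0.01 turned to 0.02 with equal array medians. F3 was at 0.25 and 0.40, and KRT5 at a mean of 0.07, which turned to -0.04 under quantile scaling.

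By limma 0 of 7836 genes passed in HBEC (lowest adjusted p 0.397), with 670 at an unadjusted p under 0.05 against 392 expected, and with no replicate block 0 passed as well. With a mean-variance trend 2 genes passed, CCL20 and ID3. Adjusted over the list alone, CCL20 and IL1A passed among cytokines, EREG, PHLDA1 and TGFA among EGF receptor ligands and SRF among immediate early genes, beside 0 over all genes. So did ID3 among TGF-beta and matrix genes, CTNNB1 among Notch and Wnt genes and CDH5, dim in HBEC, among endothelial markers. Without either summer HBEC array 0 lists were called, without either winter HBEC array 7, and without the members of largest difference 2.

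The cell type comparison asks whether APM moved a gene differently in endothelium and epithelium. CCL20 (-1.74 ± 0.29, HAEC minus HBEC), IL1A (-1.17 ± 0.28) and EREG (-1.06 ± 0.23) leaned to HBEC, and VIPR1 (1.46 ± 0.26) to HAEC. IL1A and EREG are dim in HAEC, while CCL20 in HAEC went from 48.7 to 46.1 in summer and from 14 to 12.1 in winter. None passed over all genes: limma called 0 of 7836 (lowest adjusted p 0.785), with 472 at an unadjusted p under 0.05 and 0 called with no replicate block. Adjusted over the list alone, CCL20, IL1A, SELE, EREG, ID3, COL1A2 and FAP passed. Of 30 lists 0 were called (lowest adjusted p 0.189, fibroblast markers); 1 was called without either summer HBEC array or either winter HAEC array, and 2 without either winter HBEC array.

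Over both cell types the question is which genes move with APM in all 4 pairs. Not every gene of this ranking is used here. PTGS2 was higher in every pair, from 0.38 in winter HBEC to 1.24 in summer HAEC (mean 0.82 ± 0.13, adjusted p = 0.49). F3 (0.50 ± 0.11) was also higher in all 4 pairs, as was CYP1A1 (1.30 ± 0.29), whose summer HBEC difference was 0.11. AP1G2, a vesicle coat subunit, was lower in all 4 (-0.59 ± 0.09), and PYCR3 lay at -0.68 ± 0.16.

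Over all 4 pairs 9 lists rose and 0 fell. For NF-kB targets (adjusted p = 3e-05; adjusted p = 0.242 with an estimated correlation) 4 of 15 members were higher in every pair, where chance gives 6.25%, and for immediate early genes (adjusted p = 3e-05; adjusted p = 0.242 with an estimated correlation) 6 of 25. Cytokines and chemokines rose (adjusted p = 0.000146; adjusted p = 0.373 with an estimated correlation) with 1 of 14 higher in every pair. CXCL2 was not that member, being at 1.11, 0.42, 0.57 and -0.06 in the summer HAEC, winter HAEC, summer HBEC and winter HBEC pairs. The unfolded protein response rose (adjusted p = 0.00301; adjusted p = 0.713 with an estimated correlation) with 1 of 23 higher in every pair, and the AhR list rose (adjusted p = 0.0219; adjusted p = 0.414 with an estimated correlation) with 3 of 13, CYP1A1, CYP1B1 and TIPARP (0.17 to 0.42). EGF receptor ligands rose (adjusted p = 0.0219; adjusted p = 0.54 with an estimated correlation) with 1 of 9. The other lists that rose were hypoxia and glycolysis genes, median 0.03 (adjusted p = 0.0443; adjusted p = 0.414 with an estimated correlation), where the glucose transporter SLC2A3 was at 0.28 to 0.45, p53 targets, median 0.09 (adjusted p = 0.0494; adjusted p = 0.56 with an estimated correlation), where PLK3 was at 0.18 to 0.39, and ribosomal proteins, median 0.03 (adjusted p = 0.0307; adjusted p = 0.826 with an estimated correlation). Oxidative stress genes of the NRF2 pathway (median 0.02, adjusted p = 0.341), metallothioneins (0.05, adjusted p = 0.263), heat shock genes (-0.01, adjusted p = 0.762), interferon genes (-0.05, adjusted p = 0.762), coagulation genes (0.02, adjusted p = 0.762) and cell cycle genes (-0.03, adjusted p = 0.196) were not called. The heat shock and interferon tests pointed upward although these 2 medians lie below 0.

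Limma called 0 genes over both cell types, with 482 at an unadjusted p under 0.05, and 0 with no replicate block; adjusted over the list alone CYP1A1, IER3, IRF1, PTGS2, SLC2A3 and ELF3 passed. The count of lists was 3 without either winter HAEC array, 4 without either summer HBEC array, 4 when each called list lost its member of largest difference and 5 with no filter. NF-kB targets, immediate early genes and cytokines were called under each of the 8 alternatives of scaling, offset, filter and probe sets, and without each array in turn. The unfolded protein response held in 8 of 8 alternatives and 4 of 8 fits with an array left out, EGF receptor ligands in 7 and 4, the AhR list in 6 and 4 and ribosomal proteins in 5 and 4. Hypoxia and glycolysis genes held in 4 and 0 (adjusted p up to 0.822) and p53 targets in 2 and 2 (up to 0.478).

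**Figure D2:**
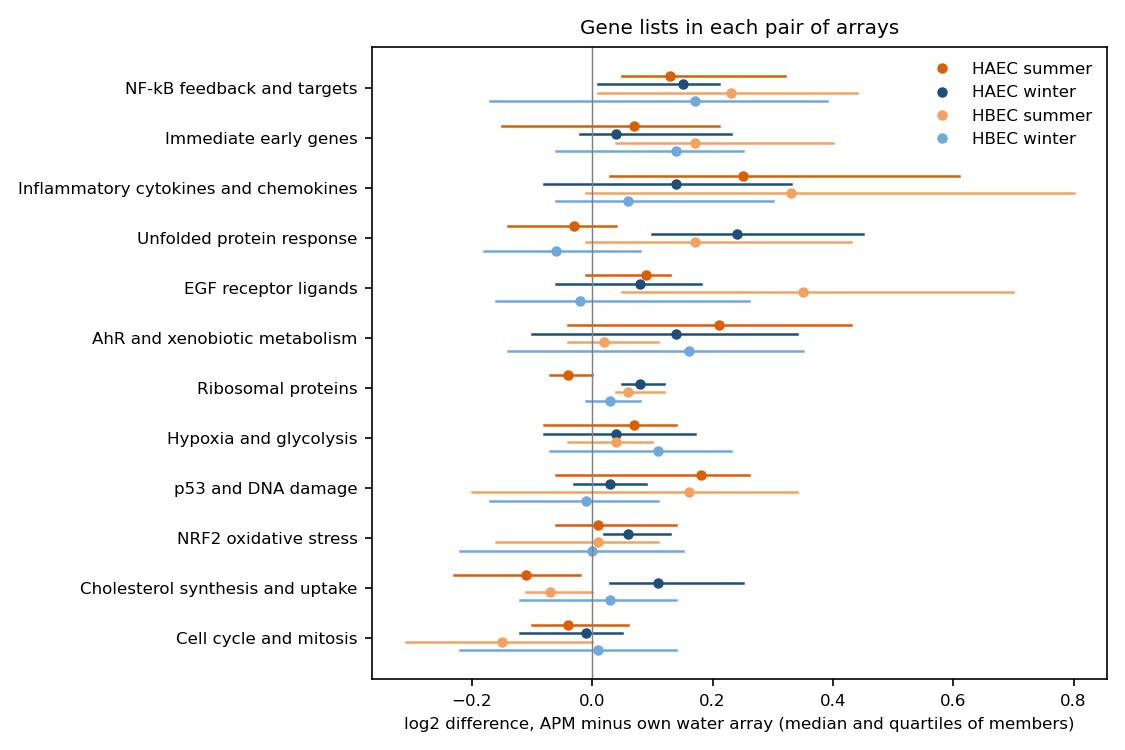
Median log2 difference (APM minus own water array; horizontal axis) of 12 gene lists in each of the 4 pairs of arrays; points are medians over the list's members and lines join the quartiles. NF-kB targets lie above 0 in every pair (0.13, 0.15, 0.23 and 0.17), while cholesterol genes lie at -0.11 and -0.07 in summer and 0.11 and 0.03 in winter.

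The season comparison asks whether summer and winter particles act alike, with the 2 cell types as its pairs. The water arrays of the seasons also differ, by 2-fold in 502 genes in HAEC and 226 in HBEC, so the season of the particles cannot be separated from the round of arrays. Among the genes of largest difference in summer were CHAC1, an enzyme that breaks down glutathione (1.24 ± 0.39), PTGS2 (1.05 ± 0.16), the phosphatase PTPN21 (0.92 ± 0.15), CXCL8 (0.92 ± 0.33), CXCL2 (0.84 ± 0.18) and TNFAIP3, an NF-kB inhibitor (0.82 ± 0.24). The HBEC pair gave most of this for CHAC1 (1.95, against 0.54 in HAEC), CXCL8 (1.64 and 0.19) and TNFAIP3 (1.31 and 0.33). The PTPN21 value rests on the probe set used, since the others did not rise in summer HBEC. They were at 0, 0.07 and -0.27 there, against 0.93 for the one used. Those at 0 and -0.27 were brighter in the summer HBEC water array (45.3 and 39.6) than the one used (18.4). In summer HAEC the others were, in the same order, at 0.52, -0.77 and 0.70, against 0.91. Among genes lower in summer, DBP, a clock transcription factor that is dim in HAEC, was at -0.85 ± 0.11. In winter the largest were CYP1B1 (1.86 ± 0.46, from 2.98 in HBEC and 0.75 in HAEC, where it is dim) and CYP1A1 (1.71 ± 0.38). The lists that rose in summer were cytokines (adjusted p = 8.72e-05; adjusted p = 0.696 with an estimated correlation), NF-kB targets (adjusted p = 0.000415; adjusted p = 0.696 with an estimated correlation), immediate early genes (adjusted p = 0.00474; adjusted p = 0.845 with an estimated correlation), p53 targets (adjusted p = 0.0262; adjusted p = 0.845 with an estimated correlation) and EGF receptor ligands (adjusted p = 0.0417; adjusted p = 0.845 with an estimated correlation). Members higher in both summer pairs were 7 of 14, 8 of 15, 11 of 25, 6 of 17 and 6 of 9.

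In winter the lists that rose were immediate early genes (adjusted p = 0.00553; adjusted p = 0.8 with an estimated correlation), NF-kB targets (adjusted p = 0.0112; adjusted p = 0.8 with an estimated correlation), ribosomal proteins (adjusted p = 0.0223; adjusted p = 0.812 with an estimated correlation), the unfolded protein response (adjusted p = 0.0229; adjusted p = 0.812 with an estimated correlation), hypoxia and glycolysis genes (adjusted p = 0.0347; adjusted p = 0.8 with an estimated correlation) and the AhR list (adjusted p = 0.0366; adjusted p = 0.8 with an estimated correlation). Members higher in both winter pairs were 10 of 25, 6 of 15, 23 of 34, 9 of 23, 11 of 23 and 6 of 13. The mean shift of ribosomal proteins, 0.056, turned to -0.033 under quantile scaling. Unfolded protein response genes had a mean of 0.301 in the winter HAEC pair alone and -0.086 in the winter HBEC pair alone.

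Tested directly as winter minus summer, 1 list of 30 differed. Genes of cholesterol synthesis and uptake were higher in winter than in summer (median 0.13, adjusted p = 0.045; adjusted p = 0.914 with an estimated correlation), with 8 of 20 members higher in both cell types, 1 lower, and chance at 25% each way. MVD, which makes an isoprenoid precursor of sterols, differed by 1.11 ± 0.37, mostly from a summer HAEC difference of -1.27, from 24.6 in the water array to 1.78, which is at background, in the APM array. EBP, a sterol isomerase, differed by 0.48 and turned to -0.15 without the less specific probe sets. Fibroblast and smooth muscle markers (median -0.19, 7 of 10 members lower in winter in both cell types, adjusted p = 0.0601) and cytokines (median -0.28, adjusted p = 0.0784) leaned to summer without passing. CYP1B1 differed by 1.26 and CYP1A1 by 0.83, but CYP1A1 leaned to winter in HBEC alone (0.11 in summer, 2.21 in winter) and to summer in HAEC (1.65 and 1.22).

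By limma 0 genes passed in summer, 0 in winter and 0 for the season difference, with 469, 300 and 288 at an unadjusted p under 0.05. Adjusted over the list alone, CXCL2 and PTGS2 passed in summer and CYP1A1 and CYP1B1 in winter. Without either summer HBEC array 7 genes and 2 lists were called in summer, against 0 and 5; without any 1 of the 4 summer arrays 1 gene, CYP1A1, was called in winter; and without either winter HAEC array 0 lists were called in winter, against 6. The season difference had 0 lists without either winter HAEC array, 2 without either summer HBEC array and 3 without either array of the summer HAEC or the winter HBEC pair. With no replicate block 1 list was called in winter and 0 for the season difference.

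Each single pair sets 1 APM array beside its own water array, so its values have no error and no test. In summer HAEC 23 genes were at least 2-fold higher and 9 at least 2-fold lower, led by CYP1A1 and VIPR1, and in winter HAEC 5 and 0, with CYP1A1 among them. In summer HBEC there were 17 and 13, with CCL20 at 2.10, CHAC1 at 1.95 (from 12.5 to 89.2, but at background in both winter HBEC arrays), CXCL8 at 1.64 and EREG at 1.49. In winter HBEC there were 7 and 10, with CYP1B1 at 2.98, CYP1A1 at 2.21 and CCL20 at 1.22, while the mitochondrial gene COA7 was at -1.46 and the DNA repair gene APEX2 at -1.36. Unfolded protein response genes had a median of 0.24 in winter HAEC and 0.17 in summer HBEC, both at the 100th percentile of random lists, and -0.03 and -0.06 in the other 2 pairs. Metallothioneins, which bind metals, had a median of 0.19 in winter HAEC (100th percentile) and -0.07 in winter HBEC. Marker lists differed too: in winter HBEC the squamous markers had a median of 0.23 (100th percentile) and the fibroblast markers -0.30 (percentile 0.05), and in summer HBEC the ciliated and secretory markers -0.33 (percentile 0.085). The random lists were not matched on correlation between genes. Its estimate in the fits by cell type was 0.69 for metallothioneins, 0.727 for ciliated and secretory markers and 0.421 for fibroblast markers. For unfolded protein response genes it was 0.352, and for squamous markers 0.096. Percentiles of lists with a high estimate may be too extreme.

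The seasons were also compared gene by gene within each cell type. In HAEC 16 genes differed at least 1.5-fold the same way in both seasons and 2 in opposite ways; 10 were higher, among them CYP1A1, PTGS2, SELE, VIPR1, HTR2B and the bacterial flagellin receptor TLR5, which is dim in HAEC. In HBEC 29 went the same way and 13 opposite ways, with CCL20, EREG, IL1A, IL1B, CLDN4, SRF, WNT7B and CYP1B1 higher and ID3, CD320 and FAP lower. Among genes that are not dim in their cell type the counts were 9 and 0 in HAEC and 18 and 9 in HBEC. Across all genes the summer and winter differences had a Pearson r of 0.091 in HAEC and 0.086 in HBEC, against 0.009 to 0.047 between cell types. By rank the HAEC value was only 0.048 and the HBEC value 0.084, against -0.008 to 0.033 between cell types; genes are not independent replicates.

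**Figure D3:**
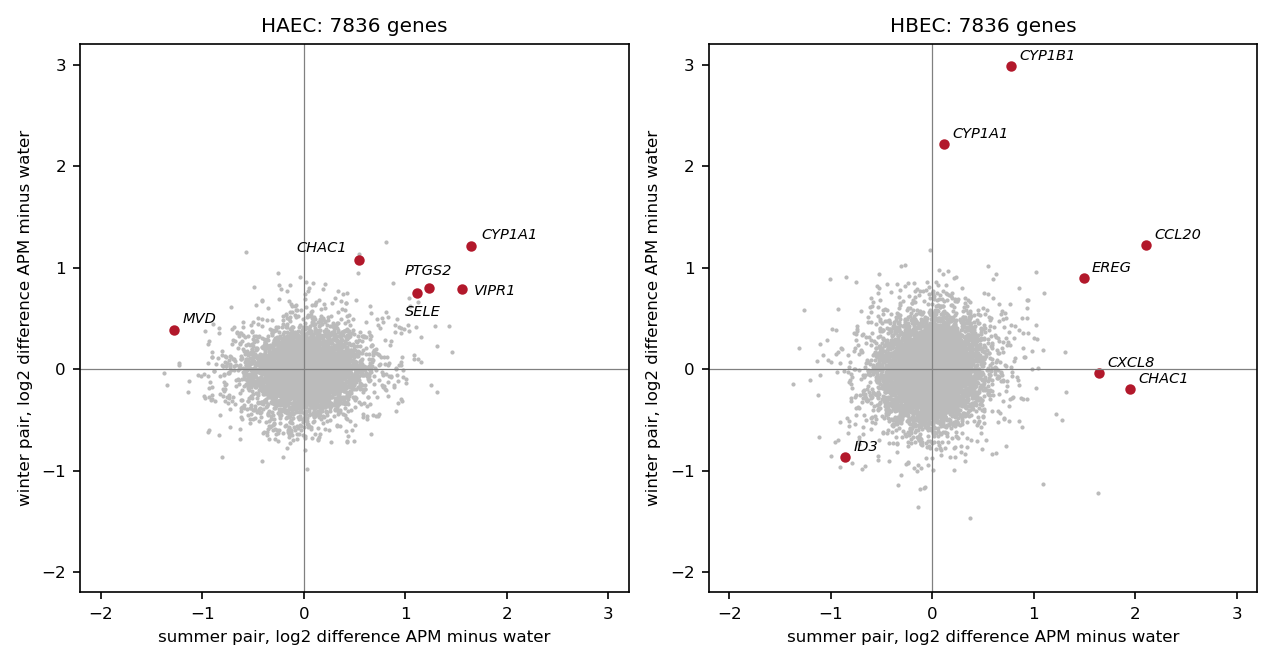
Log2 difference (APM minus water) of each of 7836 genes in the summer pair (horizontal axis) and the winter pair (vertical axis) of HAEC (left) and HBEC (right); each point is a gene and the named genes are in red. CYP1A1 lies at 1.65 and 1.22 in HAEC and at 0.11 and 2.21 in HBEC, and CXCL8 in HBEC at 1.64 and -0.04.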

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

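The tests of the other CYP1B1 probe sets and of the HBEC water arrays were chosen only after the results were seen. So was the comparison of HAEC differences across levels of brightness. The test among bright HAEC genes and its bound were set beforehand.

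The genes of cholesterol synthesis and uptake drew attention because their APM effect differed between the seasons in a direct test (median difference 0.13, adjusted p = 0.045; adjusted p = 0.914 with an estimated correlation). The adjusted p ran from 0.0196 to 0.928 over 8 alternatives of processing, 4 of which kept the call, and it was 0.183 with no replicate block and 0.0784 without MVD, its member of largest difference. Without either winter HAEC array 0 lists differed between the seasons. No group has 4 or more arrays, so no single array could be tested against its group.

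The rise of 9 lists over both cell types is the broadest pattern, and the design names the particles as its biological explanation. Camera with an estimated correlation called 0 of these lists (lowest adjusted p 0.242). Of the 32 splits of 4 against 4 arrays that could be fitted, 3 gave 9 or more lists, the real one included, and the highest of the others also gave 9. Those 2 others are 1 fit counted under 2 names. They set water against APM in the summer HBEC and winter HAEC pairs, so they hold the treatment itself and are no reference for chance. Among the 8 splits that part all 4 pairs, the real one gave 9 and the highest other 6, and 8 splits are too few for a share under 0.05. The split with 6 turns round the summer HAEC pair alone and keeps the treatment in the other pairs, so its count is no chance level either.

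The differences of CYP1A1 and CYP1B1 were larger in winter than in summer HBEC, by 2.10 and 2.21 log2 units. Scaling between arrays is argued against, since quantile scaling or equal medians moved these differences by at most 0.11. A single faulty probe set is argued against for CYP1B1 alone, whose 3 other probe sets had a median difference of 2.36. CYP1A1 has no other probe set, so a faulty one could not be tested there. A higher level in the summer HBEC water array remains possible as the explanation: it exceeded the winter water array by 1.72 for CYP1A1 and 1.52 for CYP1B1. All genes have an SD of 0.431 between the water arrays, so most of both differences lies in the controls. The APM arrays differed by 0.38 and 0.69, winter above summer, where all genes have an SD of 0.418 between these arrays. With 1 array per condition, a stronger winter response and a raised summer control cannot be told apart, and an effect of the season's particles stays open and untested.

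The summer HAEC pair had 32 genes at 2-fold and the winter HAEC pair 5, and the summer arrays were the dimmer ones. Among bright genes the SD of summer differences was 1.17 times that of winter (bootstrap interval 1.11 to 1.23 over 2000 resamples of the genes). This interval holds no spread between arrays, since each season has 1 pair. Its lower end passed the bound of 1.1 set beforehand for arguing against noise. That verdict was set aside after the values were seen, because the bound was too lenient: the ratio falls steadily with brightness, from 1.42 through 1.37 and 1.32 to 1.17, and only 2 and 1 of the 3034 bright genes reached 2-fold in summer and winter. Noise of the dimmer arrays may therefore account for much of the excess, and with single arrays it cannot be told apart from a stronger summer response.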

How the results depend on the processing

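Called lists without their member of largest change and the filter on the cell type's own arrays were chosen after seeing the data. No APM contrast gave a called gene under scaling, offset, filter or probe set alternatives or with no replicate block, and the directions of named genes held except where given here; the baseline count stayed within 1.5 times except without the less specific probe sets and without the winter HAEC water array. NF-kB targets, immediate early genes and cytokines over both cell types were called under all 8 alternatives of processing (highest adjusted p 0.00272, 0.00253 and 0.0355) and in all 8 fits with 1 array left out (0.00235, 0.00451 and 0.00333). Of the 29 list calls, 29 held with the 20% offset, 27 with equal array medians and 23 with quantile scaling. With the mean of all probe sets 23 held, with the 60th percentile filter 22 and with the 2% offset 21. With no filter 18 held, and also 18 without the less specific probe sets. Finally, 19 held with no replicate block, 13 without the member of largest change and 0 with an estimated correlation. That last loss follows partly from its construction, since the estimated-correlation test has 2 or 3 degrees of freedom. For some lists the estimate was also far above the preset 0.01. Over both cell types it was 0.293 for the unfolded protein response and 0.361 for ribosomal proteins. It was -0.036 for NF-kB targets, 0.007 for immediate early genes and 0.051 for cytokines. Where the estimate is high, the preset test may give p-values that are too small. Where no reason is given the cause was not tested. Signal over background limits the fold counts, since dim genes lie near the background level of the array.

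Counts of called lists are given here in the order HAEC, HBEC, both cell types, summer, winter and season difference, with 4, 4, 9, 5, 6 and 1 as reported; contrasts left unnamed stayed within 1.5 times. An estimated correlation gave 0 in each. Without the member of largest change HAEC had 0, HBEC 2, both cell types 4, summer 3 and the season difference 0. The 2% offset gave 0 in HAEC, 2 in HBEC and 0 for the season difference, and the 20% offset 8 in summer and 3 for the season difference. Without the less specific probe sets HAEC had 2, winter 2, the season difference 0 and the cell type difference 1. No filter gave 5 over both cell types, 2 in winter and 0 for the season difference, and the 60th percentile filter 2 for the season difference. The mean of all probe sets gave 9 in HBEC and 0 for the season difference. Quantile scaling gave 3 in winter and 3 for the season difference, and equal medians 3 for the latter. No replicate block gave 1 in winter and 0 for the season difference.

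Counts of genes: a mean-variance trend called 2 in HBEC, and the baseline had 1831 without the less specific probe sets. Genes at 2-fold in the summer HAEC, winter HAEC, summer HBEC and winter HBEC pairs, with 32, 5, 30 and 17 as reported, were 294, 120, 268 and 267 at 1.5-fold, 237, 93, 172 and 159 with the 2% offset, 8, 1, 10 and 6 with the 20% offset, 70, 15, 65 and 33 with no filter, and 9, 1, 17 and 6 with the 60th percentile filter. The filter on the cell type's own arrays gave 20 and 3 in the HAEC pairs. The mean of all probe sets gave 21 in summer HAEC and 18 in summer HBEC, and leaving out the less specific probe sets 21, 17 in summer HBEC and 9 in winter HBEC.

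Genes that went the same way and opposite ways in both seasons, 16 and 2 in HAEC and 29 and 13 in HBEC as reported, were 1 and 0, and 1 and 2, at 2-fold. They were 68 and 44, and 102 and 79, with the 2% offset; 5 and 0, and 12 and 5, with the 20% offset; 33 and 13, and 45 and 41, with no filter; and 3 and 1, and 18 and 4, with the 60th percentile filter. The own-array filter gave 9 and 0 in HAEC and 18 same-way genes in HBEC. Opposite genes in HAEC were 0 with the mean of all probe sets and 1 with quantile scaling, and same-way genes in HBEC 17 without the less specific probe sets.

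Some directions turned, and the value as reported is given after each. The mean of all probe sets gave EGFR over both cell types -0.01 (0.17), PECAM1 0.01 in HAEC (-0.02) and -0.01 in HBEC (0.09), and in summer TGFA -0.03 (0.29) and TNFRSF10B -0.03 (0.26). HMOX1 in HBEC (-0.01) was 0.02 with equal medians and 0.01 with the 2% offset, where PECAM1 in HBEC was -0.01. KRT5 in HBEC was -0.04 with quantile scaling (0.07), and ribosomal proteins in winter -0.033 (0.056). Without the less specific probe sets EBP was -0.15 (0.48) and RGS5 0.11 (-0.89) in the season difference, which are the largest of these turns.

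Leaving out either array of a pair gives the same paired fit, because the other array of the pair then informs no contrast; the contrast within a cell type or season then rests on 1 pair, assumed to vary like the others. Called lists ran from 1 (without a winter HAEC array) to 6 (summer HAEC) in HAEC, from 0 (summer HBEC) to 7 (winter HBEC) in HBEC, from 0 (summer HAEC) to 2 (winter HBEC) in the cell type difference, and from 3 (winter HAEC) to 10 (winter HBEC) over both cell types. They ran from 2 (summer HBEC) to 7 (summer HAEC) in summer, from 0 (winter HAEC) to 9 (any summer array) in winter and from 0 (winter HAEC) to 3 (summer HAEC or winter HBEC) in the season difference. Called genes ran from 0 to 7 (summer HBEC) in summer, from 0 to 1 (any summer array) in winter and from 2057 (winter HAEC water) to 2834 (either HBEC APM array) at baseline. In HAEC, DNAJC3 ran from -0.07 to 0.63 and the unfolded protein response from 0.007 to 0.301, lowest without a winter array. In HBEC, CXCL8 ran from -0.04 to 1.64, TNFAIP3 from -0.22 to 1.31, HBEGF from -0.19 to 1.02 and PECAM1 from -0.20 to 0.38, each lowest without a summer array, and HMOX1 from -0.34 to 0.33 and KRT5 from 0 to 0.14, lowest without a winter array. Over both cell types ASNS ran from -0.05 (summer HBEC) to 0.54 (winter HBEC). In summer CCL20 ran from -0.06 to 2.10, SRF from -0.04 to 0.93 and HBEGF from -0.29 to 1.02, each lowest without a summer HBEC array. In winter CHAC1 ran from -0.20 to 1.07, PSAT1 from -0.09 to 0.69 and the unfolded protein response from -0.086 to 0.301, each lowest without a winter HAEC array.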

Other observations

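The test of the stress genes in this part was chosen only after the values were seen.

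Within a cell type, the summer and winter arrays differed in far more genes than the APM and water arrays of 1 season. At 2-fold, 502 genes differed between the water arrays in HAEC and 226 in HBEC, and the labels do not say whether these arrays come from separate cultures. In HBEC, cell cycle and mitosis genes were lower in winter by a median of -0.87 in the water arrays and -0.78 in the APM arrays, with 32 of 34 members lower in both. The division genes CEP55 and NUSAP1 were at -1.56 and -1.51 in water. The matrix metalloproteases MMP9 and MMP10 were higher in winter HBEC (2.55 and 2.12 in water, 2.32 and 2.50 with APM), and CYP26B1, which breaks down retinoic acid, was lower (-1.98 in water, -2.36 with APM). ID3, which was lower with APM in both HBEC pairs, was 1.39 higher in the winter water array than in the summer one.

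In HAEC, fibroblast and smooth muscle markers were lower in winter (median -1.09 in water, -1.36 with APM, 6 of 8 members lower in both), as were TGF-beta and matrix genes (-0.62 and -0.64, 16 of 21 members) and all 34 ribosomal proteins (-0.66 and -0.49). Other abundant transcripts were lower too: housekeeping genes (-0.48 and -0.45, 10 of 13 members), oxidative phosphorylation (-0.31 and -0.23, 30 of 33) and the proteasome (-0.34 and -0.31, 19 of 25). Oxidative phosphorylation lay at percentiles 6.4 and 26.1 of random lists matched on expression, so equally abundant genes lay about as low. Ribosomal proteins (percentiles 0.07 and 1.35), the proteasome (0.675 and 2.35) and housekeeping genes (2.48 and 2.39) lay below most such lists. COL1A1, a collagen of fibroblasts, was at -2.49 in water, RGS5, a pericyte marker, at -2.77, and TSPAN8 and HOPX at -4.16 and -4.20, while FBN2, a microfibril protein, was 3.45 higher in winter. Endothelial markers were higher in winter (0.32 and 0.37, 16 of 22 members) and so were cholesterol genes (0.34 and 0.63, 16 of 20 members). The APM effects above are differences from the water array of the same season, and these values have no replicate and no test. Probe sets without a single gene symbol, 1347 above the filter level in HAEC and 1396 in HBEC, held 0 and 0 with a 2-fold APM difference in both seasons, and 4 and 3 at 1.5-fold.

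A hypothesis on the unfolded protein response list is that its amino acid and integrated stress arm moved apart from its chaperone arm in the summer HBEC pair. The 11 integrated stress genes, such as CHAC1, ASNS (1.27) and DDIT3 (0.88), had a median of 0.44 there, at the 100th percentile of random lists and with 10 of 11 higher, while the 12 chaperone genes had a median of 0.02, at percentile 71.1. In winter HAEC both arms were high, with medians of 0.43 (percentile 100) and 0.13 (percentile 99.9). In summer HAEC the integrated stress median was 0.04 (percentile 70.8) and the chaperone median -0.08 (percentile 4.88, 3 of 12 higher), and in winter HBEC they were -0.09 (percentile 22.4) and -0.03 (percentile 35). The arms were drawn after genes such as CHAC1 were seen high in the summer HBEC pair, so its percentile restates that view. The difference between the arms was not tested, and the hypothesis stays open.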
